A study of Mus musculus
mouse gut metagenome and mouse gut metagenome with 20 samples.

How the data were processed

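The series holds 20 samples from mice that carried a consortium of 4 gut bacteria, named in the labels as B. thetaiotaomicron, P. distasonis, B. producta and E. bolteae. Of these, 12 are RNA libraries of cecal tissue together with the contents of the cecal pouch, so that host and bacterial transcripts were sequenced together. The other 8 samples are 16S amplicon samples (4 after PBS and 4 after flagellin), which were not analysed here, and the host transcripts were not analysed here either. The RNA libraries form 4 groups. In the injection experiment 4 libraries came 6 h after an intraperitoneal dose of 2.5 µg flagellin and 4 came after PBS by the same route. In the gavage experiment 2 libraries came 2 h after an oral dose of 50 µg oleic acid with 50 µg linoleic acid, called uLCFA (unsaturated long-chain fatty acids) in the labels, and 2 came after PBS gavage.

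Per the labels' protocols, bacterial RNA was extracted with an RNeasy PowerMicrobiome kit and host RNA with trizol. Libraries were made with a stranded total RNA kit with ribosomal RNA depletion and read on a NovaSeq 6000 as single reads of 100 bases. The submitters' processing notes name Trimmomatic, Bowtie2, featureCounts and DESeq2, without versions or settings, and the mouse build mm10. The bacterial reference assemblies, the strand setting and the handling of reads that map to several places are not given in the sources used here. Reads from near-identical genes, from overlapping genes and from antisense partners can therefore not be separated. The values used are raw counts per annotated feature, as deposited by the authors in 8 count tables, 1 per species and experiment. The tables hold 5190 features for B. thetaiotaomicron, 4784 for P. distasonis, 5997 for B. producta and 6547 for E. bolteae. Each feature has an identifier and a product name from an automated annotation, and 1828, 1734, 2500 and 2833 of them are annotated only as hypothetical proteins. Genes are given here by product name alone, with identifiers in the result tables and figures, and no coordinates are used, since no bacterial genome was used here. The columns called FFA in the gavage tables were matched to the uLCFA samples through the numbers in the sample titles. No column was left unused.

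Each species and experiment was fitted alone with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, libraries were scaled by TMM within the species' table, and the robust quasi-likelihood F-test compared treated with PBS libraries. P-values were adjusted by the Benjamini-Hochberg method within the table, and a gene was called at an adjusted p under 0.05. Because scaling is within a species, a log2 fold change is relative to the other genes of that species and does not follow the species' abundance. With 8 libraries the flagellin fits had 6 residual degrees of freedom, and with 4 libraries the uLCFA fits had 2. The SE given beside a log2 fold change is its absolute value divided by the square root of the F statistic, not a separately fitted standard error. CPM values are edgeR's TMM-scaled CPM within the species, with the SD over the libraries of a group. Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists with at least 5 tested genes in a species and comparison, and again with a correlation estimated from the libraries. Functional lists, 24 in number, were fixed before the data were examined and were matched by product name. Their name patterns were widened once the product names had been read but before any value was tested. A further 15 lists of B. thetaiotaomicron genes given by locus number could not be matched to the identifiers and are not reported. Species shares of a library's bacterial counts were compared by an exact two-sided permutation test of the difference of means. That test has 70 arrangements in the injection experiment, so its smallest p is 0.0286, and 6 in the gavage experiment, so its smallest p is 0.333. The difference between the flagellin and uLCFA responses was tested as an interaction on the 12 joined libraries. It cannot separate treatment from route, time and run, which differ between the experiments.

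The tests, the groups, the gene lists and the rule for genes named in the text were chosen before the data were examined. The rule takes, per species and comparison, called genes whose CPM ranges do not overlap between the groups, with at least 10 counts in every library of the higher group and a product name. Among these it takes the 3 largest rises and 3 largest falls, and then up to 3 called members with the smallest p of each list that passed its test or held at least 3 called genes. Without a call, the 2 genes with the smallest p are given as values, and at most 2 hypothetical proteins that rose and 2 that fell may be named. From the genes the rule gave, examples that stayed called when any 1 library was left out were preferred. Alternatives were DESeq2 1.42.0, RLE size factors, library totals alone, no expression filter, a minimum of 10 counts in every library, a replicate block, a joint fit of the 12 libraries, the omission of annotated ribosomal and transfer RNA, other set tests, and the omission of each library in turn. Thinning of every library to the smallest total, the omission of features above 5% of a library, the lists as first written and a list of ammonium assimilation genes were added after the data had been seen.

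Counts were simulated at the PBS libraries' means and the real library sizes. In the flagellin design 92.3%, 89.1%, 93.9% and 60.2% of genes changed 4-fold were called for B. thetaiotaomicron, P. distasonis, B. producta and E. bolteae (91, 92, 99 and 88 changed genes). Of genes changed 2-fold, 16.8%, 22.6%, 19.8% and 4.35% were called. False calls were 1 of 101, 2 of 105, 8 of 120 and 0 of 57. The rise of features above 5% of a library was not simulated. It left fewer counts to other genes in the real flagellin libraries, so these rates may be too high. In the uLCFA design the only false calls were 2 of 17, in P. distasonis. In the uLCFA design 1.10%, 14.6%, 0% and 0% of genes changed 4-fold were called, and in the interaction design 5%, 26%, 6% and 0%. A missing call in the gavage experiment is therefore weak evidence. No 2 libraries of a group were alike within sampling noise, the lowest chi-square per degree of freedom being 3.26. The labels number the replicates of each group but do not say whether they are separate animals, so p-values measure the spread between these samples. Where a gene had no count in a group, the fold is given against 3 counts over the group. Where it had 1 to 3 counts, the ratio is given with an exact 95% interval. Such bounds cover counting error only. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.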

Results

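Transcripts of 4 cecal bacteria were measured by RNA sequencing after systemic flagellin, the flagellar protein that host innate receptors sense, and after an oral dose of oleic and linoleic acid. The series' title links such fatty acids to signals between host and microbes during immune responses, so the comparisons ask how the bacteria responded to an immune stimulus and to the fatty acids themselves. Over the 4 species, the PBS injection libraries held 3533030, 4540816, 2984996 and 2816524 counts and the flagellin libraries 1837723, 2580620, 1135192 and 1520707. The PBS gavage libraries held 4588919 and 4523743 counts and the uLCFA libraries 7058653 and 8310465. Depth differed most in B. thetaiotaomicron, with 84674 to 110915 counts per flagellin library against 295397 to 459015 per PBS injection library, and E. bolteae was shallow after flagellin, with 54193 to 150884.

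After flagellin, B. producta made up 73.2% ± 8.98 of the bacterial counts (SD, n = 4) against 54.6% ± 6.40 after PBS (n = 4), and P. distasonis 13.4% ± 3.22 against 24.4% ± 5.24. For both species the exact permutation p was 0.0286, the smallest possible, and 0.0571 after adjustment over the 4 species. B. thetaiotaomicron stood at 6.21% ± 2.14 against 11.6% ± 3.20 (n = 4 each, exact permutation p = 0.0571, adjusted 0.0762) and E. bolteae at 7.20% ± 4.65 against 9.39% ± 4.62 (exact permutation p = 0.486). Bacterial counts in total were 1768560 ± 612865 per flagellin library and 3468840 ± 777362 per PBS library (n = 4 each, exact permutation p = 0.0286 on log2 totals). Such totals also depend on sequencing depth and on the host part of a library, which were not examined, so they do not give bacterial amounts. The higher B. producta share lay in a few features. Without features above 5% of any library its difference fell from 18.6 to 3.88 percentage points, those of P. distasonis and B. thetaiotaomicron went to -5.53 and -0.02, and that of E. bolteae turned to 1.67.

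**Figure D1:**
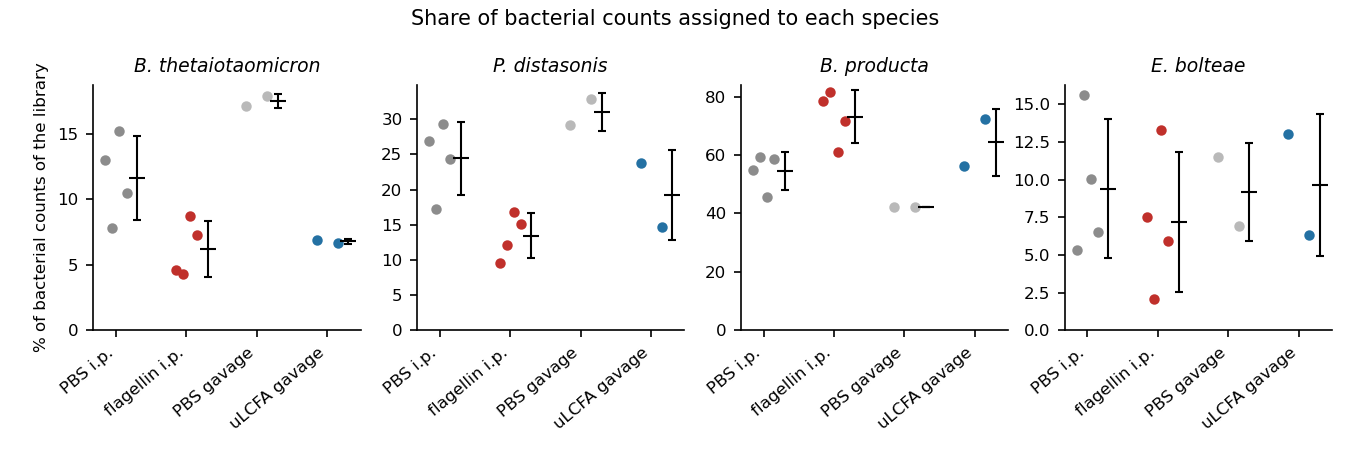
Share of each library's bacterial counts assigned to each species, in percent, for the 4 groups. Points are libraries and bars show the mean and SD. B. producta averaged 73.2% after flagellin and 54.6% after PBS injection, and 64.3% after uLCFA and 42.3% after PBS gavage.

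The features that took large parts of a species' counts were mostly unnamed genes, all singled out after their values were seen. Of those given here, only the pair of B. producta hypothetical proteins could have raised the B. producta share. The others belong to other species or fell. Of B. producta counts, 1 hypothetical protein took 37.8% ± 3.33 after flagellin and 11.1% ± 1.92 after PBS (n = 4 each), and the next feature in the table, also a hypothetical protein, took 29.5% ± 3.63 and 7.68% ± 0.982. Both rose (log2 3.36, SE 0.32 and 3.55, SE 0.32, edgeR adjusted p = 6.24e-05 and 4.92e-05). In P. distasonis a hypothetical protein took 32.0% ± 11.0 against 6.35% ± 2.10 and rose by 2.80 (SE 0.45, adjusted p = 0.00103). In B. thetaiotaomicron a hypothetical protein took 5.80% ± 0.229 against 1.21% ± 0.0965 and rose by 2.39 (SE 0.21, adjusted p = 2.77e-06). In E. bolteae a hypothetical protein took 14.4% ± 15.0 against 0.247% ± 0.161, with 0.380% to 35.1% among the 4 flagellin libraries. Amidophosphoribosyltransferase, a purine synthesis enzyme of B. producta, took 0.149% ± 0.149 against 3.09% ± 1.97.

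**Figure D2:**
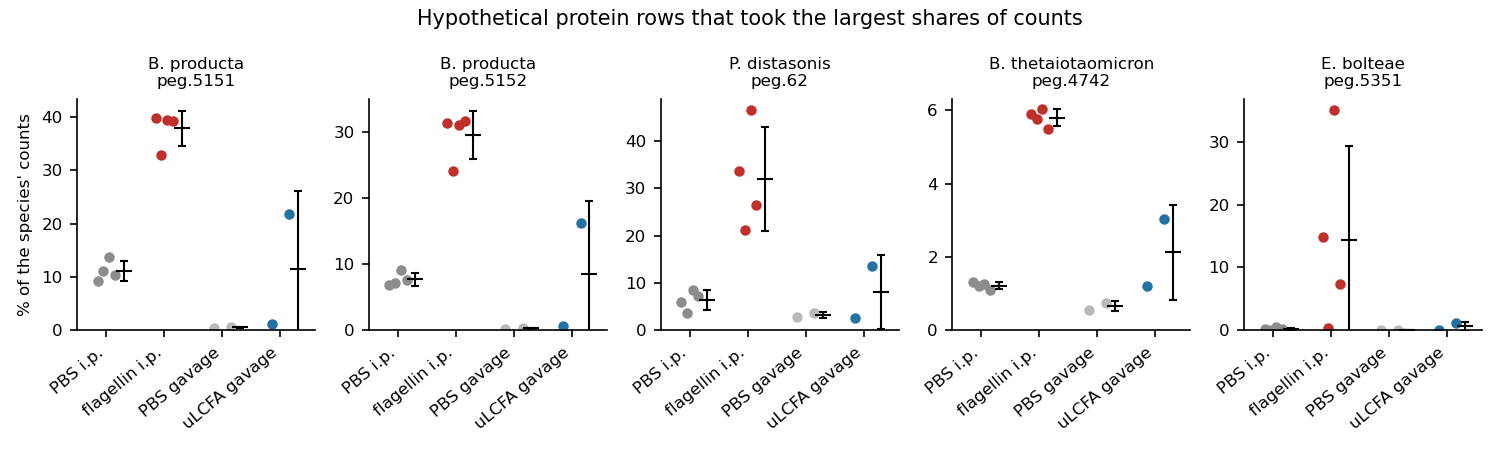
Percent of a species' counts taken by 5 hypothetical proteins in the 12 libraries. Points are libraries and bars show the mean and SD, with the axis starting at 0. In the first panel the B. producta feature lies between 32.9% and 39.8% in the flagellin libraries, and after PBS injection between 9.30% and 13.8%.

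In B. thetaiotaomicron flagellin changed 585 of 2477 tested genes, 319 upward and 266 downward. Among named genes the largest rises were in the succinyl-CoA ligase subunits of central carbon metabolism, alpha (log2 3.25, SE 0.38) and beta (3.17, SE 0.34). NAD-specific glutamate dehydrogenase, which interconverts glutamate with alpha-ketoglutarate and ammonia, followed at 3.12 (SE 0.33), from 1930 ± 478 to 16783 ± 6866 CPM (n = 4 each). The largest falls of named genes were in ammonia assimilation. Glutamine synthetase GlnN went from 4690 counts over the 4 PBS libraries to 3 over the flagellin libraries, a 372-fold lower level (interval 127 to 1803), and the small chain of glutamate synthase from 1704 to 2, 203-fold lower (56.0 to 1674). Asparagine synthetase fell to -6.88 (SE 0.56) and the large chain of glutamate synthase to -6.72 (SE 0.47). Adjusted p-values of these genes ran from 3.45e-09 to 2.69e-05. On a list of 9 ammonia assimilation genes, put together after the values were seen, 7 fell. Most of the fallen genes lie close together in the order of the identifiers, so they need not be independent. Another GlnN (-1.38, SE 0.52, edgeR adjusted p = 0.0706) and glutamine synthetase type I (0.25, SE 0.31, adjusted p = 0.599) were not called.

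Some enzymes that remove reactive oxygen rose as well. Of 15 tested oxidative stress genes 6 rose and 0 fell (7 and 1 adjusted over the list alone), among them superoxide dismutase (log2 2.65, SE 0.23), thiol peroxidase (2.77, SE 0.32) and a glutathione peroxidase (2.59, SE 0.39). The list passed camera (adjusted p = 0.0058) but not with its own correlation (adjusted p = 0.375 with an estimated correlation). Sigma factors and other stress regulators rose as a group, 23 of 41 and 0 downward (24 and 0 adjusted over the list alone), with an extracytoplasmic function sigma factor at 1.83 (SE 0.25) and a putative anti-sigma factor at 2.20 (SE 0.30). This list kept its call (camera adjusted p = 4.7e-08, and adjusted p = 0.0304 with an estimated correlation), as did amino acid synthesis, where 23 of 58 genes fell and 3 rose (31 and 3 adjusted over the list alone, adjusted p = 4.96e-08, and adjusted p = 0.0304 with an estimated correlation). The F-type and V-type ATP synthase genes split, with 9 of 16 rising, such as the beta chain (1.61, SE 0.24), and 4 falling, and that list did not pass (adjusted p = 0.184). Of 102 SusC and SusD proteins, the outer membrane glycan importers, 22 fell and 9 rose (also 22 and 9 adjusted over the list alone, camera adjusted p = 0.184). Of 120 glycoside hydrolases and sulfatases 23 fell and 9 rose (25 and 12 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0807). Its members included a pair of alpha-1,2-mannosidases that fell to -3.78 (SE 0.39) and -3.46 (SE 0.40).

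Further lists of B. thetaiotaomicron were called downward at the preset correlation only. Of 53 ribosomal protein genes 11 fell and 1 rose (14 and 1 adjusted over the list alone), with S4 at -1.29 (SE 0.25), and camera gave an adjusted p = 0.0124 (adjusted p = 0.643 with an estimated correlation). In purine and pyrimidine synthesis 5 of 31 fell (4 adjusted over the list alone), led by the large chain of carbamoyl-phosphate synthase (-1.93, SE 0.24), with an adjusted p = 0.0058 (adjusted p = 0.375 with an estimated correlation). For aminoacyl-tRNA synthetases and translation factors 1 of 32 fell (0 adjusted over the list alone) at an adjusted p = 0.0289 (adjusted p = 0.467 with an estimated correlation), a call that also ended with the list as first written. The calls of the ribosomal and the aminoacyl-tRNA lists ended without PBS replicate 1 (adjusted p = 0.0582 and 0.0613), without flagellin replicate 3 (0.0529 and 0.0529) and without flagellin replicate 4 (0.111 and 0.128). The joint fit of all 12 libraries called 371 genes.

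In P. distasonis 488 of 3070 genes changed, 234 upward and 254 downward. Among named genes the rises were largest for an extracytoplasmic function sigma factor (log2 3.13, SE 0.53) and for a pair of serpin protease inhibitors (3.03, SE 0.44 and 2.95, SE 0.49), the latter from 171 ± 70.3 to 1333 ± 1064 CPM (n = 4 each). Many glycan importers fell. Of 83 SusC and SusD proteins 40 fell and 1 rose (49 and 3 adjusted over the list alone), with a pair of SusC proteins at -4.26 (SE 0.54) and -4.13 (SE 0.42) and a SusD protein at -3.82 (SE 0.36). Camera gave this list an adjusted p = 2.44e-12, and adjusted p = 0.196 with an estimated correlation. Of 96 glycoside hydrolases and sulfatases 17 fell and 1 rose (20 and 2 adjusted over the list alone), such as an alpha-1,2-mannosidase (-2.57, SE 0.42), at an adjusted p = 0.00329 (adjusted p = 0.265 with an estimated correlation).

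Amino acid synthesis fell in P. distasonis too, with 25 of 77 genes lower and 1 higher (35 and 1 adjusted over the list alone, camera adjusted p = 1.15e-08, and adjusted p = 0.265 with an estimated correlation). Its members included a pair of GlnN glutamine synthetases (-4.07, SE 0.42 and -2.64, SE 0.29) and asparagine synthetase (-3.63, SE 0.40). O-acetylhomoserine sulfhydrylase, which makes methionine precursors, fell to -4.16 (SE 0.71), and the tryptophan synthase alpha chain went from 177 counts to 2, 19.8-fold lower (interval 5.41 to 165). Stress regulators rose, 15 of 41 and 0 downward (19 and 0 adjusted over the list alone, adjusted p = 2.53e-08, and adjusted p = 0.265 with an estimated correlation), as did oxidative stress genes, 7 of 22 and 0 downward (8 and 1 adjusted over the list alone, adjusted p = 0.00264, and adjusted p = 0.417 with an estimated correlation), including thioredoxin (1.70, SE 0.33) and thiol peroxidase (1.54, SE 0.33). Mobile elements were called upward with 10 of 90 rising and 1 falling (4 and 0 adjusted over the list alone, adjusted p = 0.000932, and adjusted p = 0.619 with an estimated correlation). Their median of 0.26 was smaller than the shift of -0.33 that scaling on library totals gave all P. distasonis genes.

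Among the weaker P. distasonis lists, ribosomal proteins were called downward although 0 of 54 passed alone (adjusted p = 0.000932, and adjusted p = 0.766 with an estimated correlation). Respiratory complexes were called with 1 of 18 lower (0 adjusted over the list alone, adjusted p = 0.0187, and adjusted p = 0.622 with an estimated correlation), a call that ended without flagellin replicate 3 (0.0650). The 7 ATP synthase genes had 2 lower (3 adjusted over the list alone, adjusted p = 0.0279, and adjusted p = 0.593 with an estimated correlation). That call ended without PBS replicate 2 or 4 (0.0567 and 0.0559), and without flagellin replicate 2 or 3 (0.0827 and 0.0650). The count of changed genes was 954 without flagellin replicate 2, 306 without flagellin replicate 3, 323 without flagellin replicate 1 and 279 without PBS replicate 2. Library totals in place of TMM gave 115 risen and 376 fallen genes, and RLE factors, which shifted all genes by 0.12, gave 281 and 206.

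In B. producta 771 of 3848 genes changed, 447 upward and 324 downward. The largest named rise was oleate hydratase, which adds water to the double bond of oleic acid, with a log2 fold change of 3.97 (SE 0.67, edgeR adjusted p = 0.00311) and a level of 1480 ± 1061 CPM after flagellin against 94.3 ± 67.9 after PBS (n = 4 each). Other named rises were a lantibiotic transport protein (3.86, SE 0.79) and cytidylate kinase (3.77, SE 0.31). Further lantibiotic transporters, which carry antimicrobial peptides, rose as well (3.72, SE 0.37 and 3.22, SE 0.28), as did rubrerythrin (2.89, SE 0.24), a peroxide-reducing protein of anaerobes. Efflux and drug resistance genes, to which the transporters belong, had 18 of 77 higher and 5 lower (18 and 6 adjusted over the list alone) and did not pass as a list (camera adjusted p = 0.104).

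Of 14 ammonia assimilation genes of B. producta, a list put together after the values were seen, 6 fell and 3 rose. Falls included glutamine synthetase GlnN at -6.61 (SE 0.48), glutamine synthetase type I at -4.11 (SE 0.31) and the glutamate synthase small chain at -4.43 (SE 0.36). GlnN, this small chain and the CTP synthase given below lie close together in the order of the identifiers, so their falls need not be independent. Another small chain of glutamate synthase rose by 1.74 (SE 0.20, adjusted p = 0.000212), a large chain by 0.87 (SE 0.20, adjusted p = 0.0142) and another type I glutamine synthetase by 0.91 (SE 0.23, adjusted p = 0.0198). Such genes are part of amino acid synthesis, where 41 of 100 genes fell and 7 rose (44 and 8 adjusted over the list alone). That list kept its call (adjusted p = 1.75e-05, and adjusted p = 0.0286 with an estimated correlation). Cysteine synthase went from 814 counts to 2, 108-fold lower (interval 29.9 to 896), and CTP synthase fell to -6.15 (SE 0.68). In glycolysis and fermentation 17 of 36 fell and 3 rose (20 and 3 adjusted over the list alone, adjusted p = 0.000251, and adjusted p = 0.543 with an estimated correlation), with phosphoenolpyruvate carboxykinase at -1.41 (SE 0.21) and phosphoglycerate kinase at -1.52 (SE 0.27). Fatty acid synthesis fell in 11 of 29 genes, 0 upward (also 11 adjusted over the list alone, adjusted p = 0.0033, and adjusted p = 0.543 with an estimated correlation, and 0.104 with the list as first written), with a pair of chain-starting synthases at -2.66 (SE 0.51) and -3.26 (SE 0.66).

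Further downward calls in B. producta were aminoacyl-tRNA synthetases and translation factors, 11 of 36 lower and 1 higher (15 and 1 adjusted over the list alone, adjusted p = 0.000284), and ATP synthase, 5 of 23 lower (7 adjusted over the list alone, adjusted p = 0.000485). Purine and pyrimidine synthesis had 3 of 37 lower (1 adjusted over the list alone, adjusted p = 0.00011) and ribosomal proteins 1 of 55 (also 1 adjusted over the list alone, adjusted p = 0.00018). All 4 were lost with their own correlation (adjusted p = 0.543, and for ribosomal proteins adjusted p = 0.673, with an estimated correlation). Without TMM scaling all genes shifted by a median of -1.49, 2969 genes were called, 83 upward and 2886 downward, and 230 of the 771 genes turned sign. Omitting 1 library gave 1256 called genes without flagellin replicate 2, 503 without flagellin replicate 1, 508 without PBS replicate 3 and 480 without PBS replicate 2.

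In E. bolteae 392 of 2235 genes changed, 233 upward and 159 downward. Rises of named genes included a transposon integrase (log2 4.05, SE 0.84), L-ribulose-5-phosphate 4-epimerase (3.76, SE 0.56) and the repressor of arabinoside utilization (3.61, SE 0.65), the latter pair acting in arabinose catabolism. The ammonium transporter had 927 counts over the 4 PBS libraries and 0 after flagellin, at least 55.7-fold lower against 3 counts over the group, and the large chain of glutamate synthase went from 1915 to 2, 173-fold lower (interval 47.7 to 1426). Glutamine synthetase GlnN fell to -4.18 (SE 0.74, edgeR adjusted p = 0.00847), while a pair of glutamate synthase small chains rose by 1.67 (SE 0.48, adjusted p = 0.0326) and 1.79 (SE 0.41, adjusted p = 0.0135). Iron and heme acquisition rose with 8 of 20 higher and 2 lower (10 and 2 adjusted over the list alone, camera adjusted p = 0.0112, and adjusted p = 0.637 with an estimated correlation), and a pair of ferric iron-binding proteins stood at 3.63 (SE 0.73) and 2.80 (SE 0.57). Among spore genes a small acid-soluble protein rose by 3.13 (SE 0.47) and the coat protein CotJC by 2.73 (SE 0.47), within a list of 5 higher and 2 lower of 20 (the same counts adjusted over the list alone) that did not pass (adjusted p = 0.0745).

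Lists of E. bolteae called downward at the preset correlation were all lost with their own. Of 7 respiratory complex genes, subunits of the ion-pumping Rnf complex among them, 6 fell (7 adjusted over the list alone), with RnfB at -1.87 (SE 0.40), and the list had an adjusted p = 0.000889 (adjusted p = 0.338 with an estimated correlation). Amino acid synthesis had 12 of 64 lower and 4 higher (15 and 4 adjusted over the list alone, adjusted p = 0.000889, and adjusted p = 0.315 with an estimated correlation). ATP synthase had 4 of 21 lower (also 4 adjusted over the list alone, adjusted p = 0.000889), fatty acid synthesis 5 of 16 (also 5 adjusted over the list alone, adjusted p = 0.0108, and 0.946 with the list as first written), aminoacyl-tRNA synthetases and translation factors 2 of 35 (0 adjusted over the list alone, adjusted p = 0.0019) and purine and pyrimidine synthesis 2 of 29 (1 adjusted over the list alone, adjusted p = 0.0312). Each of these had adjusted p = 0.637 with an estimated correlation. Ribosomal proteins were called downward with 0 of 53 passing alone (adjusted p = 0.00859, and adjusted p = 0.79 with an estimated correlation). The purine call ended without PBS replicate 1 (0.0622) and without flagellin replicate 4 (0.155), and the ribosomal call without flagellin replicate 1 (0.0692) and without flagellin replicate 3 (0.226).

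The E. bolteae count was the least stable of the 4. It was 955 without flagellin replicate 2, the shallowest library of this species. That library also correlated least with the other flagellin libraries (0.427 to 0.583 in log CPM, against 0.794 to 0.841 among those). In P. distasonis and B. producta it was the deepest flagellin library (314079 and 2102322 counts), and its omission raised the count there too. Without the other libraries that moved the E. bolteae count by more than 1.5 times, that count was 157 (flagellin replicate 1), 237 (flagellin replicate 3), 232 (flagellin replicate 4), 215 (PBS replicate 1), 118 (PBS replicate 2) and 127 (PBS replicate 3). DESeq2 called 714, a minimum of 10 counts per library left 159, and library totals gave 75 risen and 334 fallen genes after a shift of -0.70. In B. thetaiotaomicron library totals gave 265 risen and 327 fallen genes after a shift of -0.12. Called genes whose groups did not overlap numbered 520, 404, 691 and 286 in B. thetaiotaomicron, P. distasonis, B. producta and E. bolteae, and among all tested genes 662, 610, 1006 and 435, where chance gives 2.86%.

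**Figure D3:**
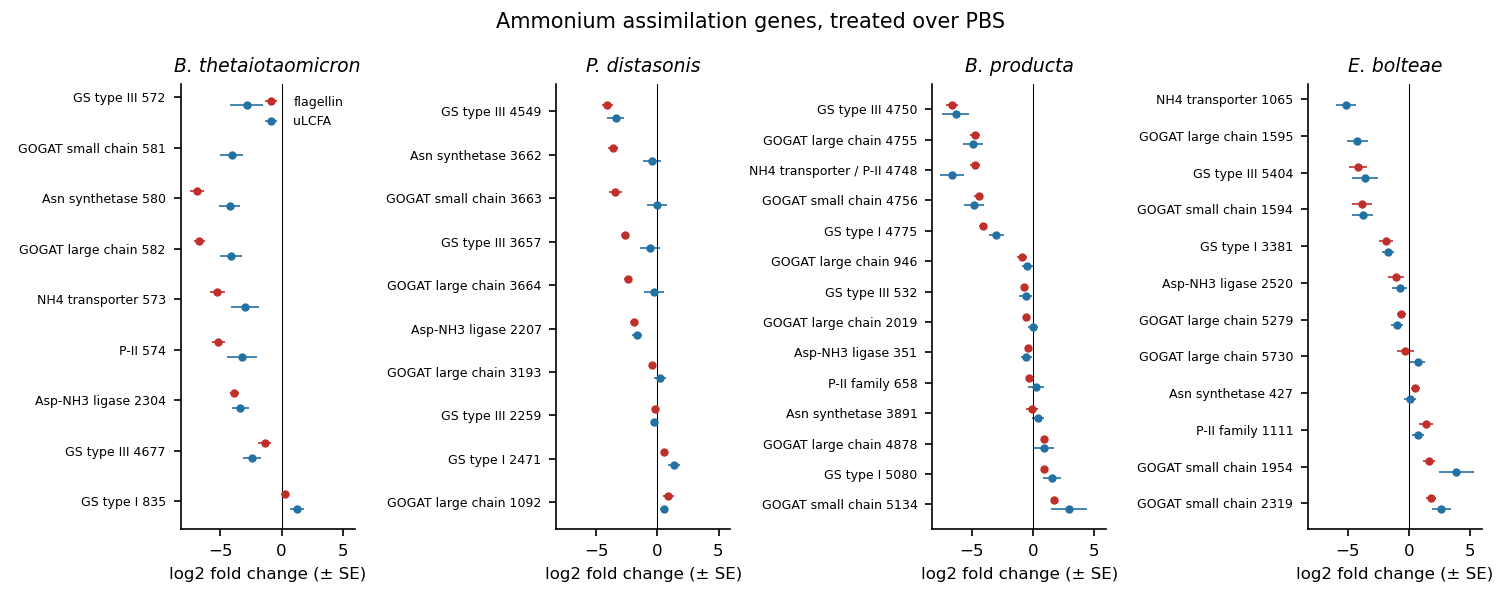
Fitted log2 fold change and SE of ammonium assimilation genes after flagellin and after uLCFA, per species, a list put together after the flagellin values were seen. Flagellin points are not drawn for a GlnN and a glutamate synthase small chain of B. thetaiotaomicron. The same holds for the ammonium transporter and a glutamate synthase large chain of E. bolteae. These genes had 0 to 3 counts over the flagellin libraries. GlnN of B. producta lies at -6.61 after flagellin and -6.34 after uLCFA.

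**Figure D4:**
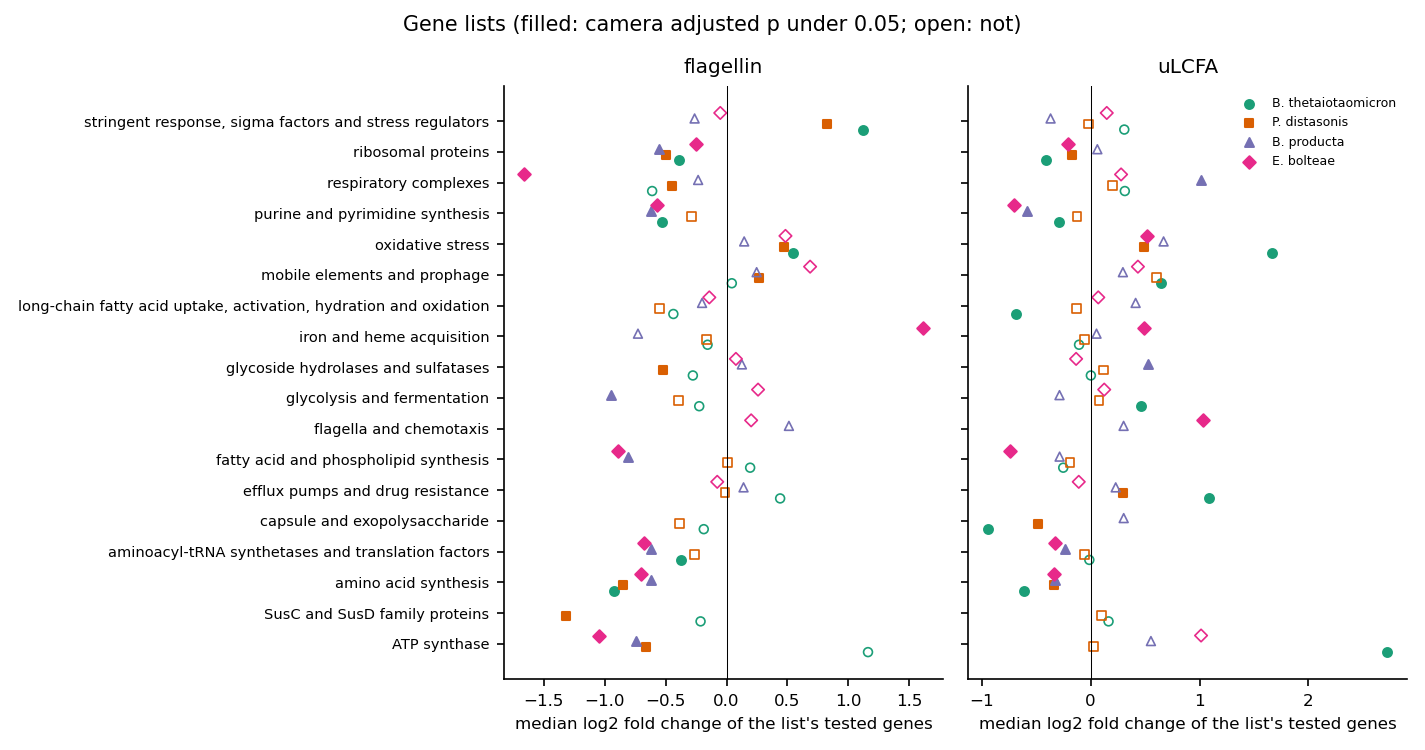
Median log2 fold change of each gene list's tested genes, per species, after flagellin (left) and after uLCFA (right). Filled symbols mark lists with a camera adjusted p under 0.05 at the preset correlation and open symbols the others. Amino acid synthesis lies below 0 in all 4 species in both panels.

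After uLCFA, B. producta made up 64.3% ± 11.3 of bacterial counts (SD, n = 2) and after PBS gavage 42.3% ± 0.0228 (n = 2). P. distasonis stood at 19.3% ± 6.40 against 31.0% ± 2.67, B. thetaiotaomicron at 6.78% ± 0.209 against 17.5% ± 0.555, and E. bolteae at 9.67% ± 4.72 against 9.19% ± 3.25. For the former 3 species the exact permutation p was 0.333, the smallest this design allows, and for E. bolteae it was 1. The most abundant hypothetical protein of B. producta after flagellin took 1.09% and 21.8% of B. producta counts in the 2 uLCFA libraries and 0.469% and 0.639% after PBS. Amidophosphoribosyltransferase took 1.26% ± 0.659 against 6.26% ± 2.62.

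No gene passed the main edgeR fit after uLCFA in any species (0 of 3520 tested in B. thetaiotaomicron, 3739 in P. distasonis, 4676 in B. producta and 3713 in E. bolteae), while 410, 295, 408 and 396 had an unadjusted p under 0.05 and DESeq2 called 225, 25, 213 and 185. The joint edgeR fit of all 12 libraries called 241, 9, 127 and 58, and edgeR without a filter 101 in E. bolteae. The smallest adjusted p-values were 0.318, 0.555, 0.0926 and 0.218. In B. thetaiotaomicron the 2 genes with the smallest p were O-acetylhomoserine sulfhydrylase, with a log2 value of -4.31 (SE 0.55), at 19.5 ± 3.13 CPM against 391 ± 15.3, and a biotin carboxyl carrier protein at 3.88 (SE 0.54). In P. distasonis the same function, O-acetylhomoserine sulfhydrylase, stood at -4.20 (SE 0.59) and a permease of unknown function at 2.21 (SE 0.32). In B. producta a pair of hypothetical proteins stood at -4.64 (SE 0.44) and -4.89 (SE 0.48). In E. bolteae the aminomethyltransferase of the glycine cleavage system stood at 4.15 (SE 0.51), and a hypothetical protein had 1 count over the PBS libraries and 130 over the uLCFA libraries, 91.8-fold higher (interval 16.2 to 3653).

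Calls appeared when 1 uLCFA library was left out, in fits that assume the lone treated library to vary like the pair of controls. Without uLCFA replicate 1 the counts were 921, 895, 1382 and 852 in the order above, and without uLCFA replicate 2 they were 627, 240, 358 and 151. Without PBS gavage replicate 1 or 2 they were 10 and 10 in B. producta, 23 and 9 in E. bolteae, 1 and 0 in P. distasonis and 0 and 0 in B. thetaiotaomicron. Library totals shifted the medians by -0.29, -0.15, -0.34 and -0.29 in the same order.

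Gene lists were called after uLCFA in 28 cases, 12 upward and 16 downward, and 0 of them with an estimated correlation, where adjusted p-values ran from 0.567 to 0.958. Of the 28, 7 kept their call and direction without any 1 library. Oxidative stress genes of B. thetaiotaomicron had a median log2 fold change of 1.67 over 20 genes (camera adjusted p = 1.12e-09, 9 higher and 0 lower adjusted over the list alone, and adjusted p = 0.844 with an estimated correlation). Superoxide dismutase stood at 3.91 and thiol peroxidase at 3.73. ATP synthase genes of the same species had a median of 2.72 over 16 genes (adjusted p = 0.0029, 9 higher adjusted over the list alone, and adjusted p = 0.844 with an estimated correlation). Purine and pyrimidine synthesis had medians of -0.59 in B. producta (adjusted p = 1.52e-06, and adjusted p = 0.958 with an estimated correlation) and -0.70 in E. bolteae (adjusted p = 4.55e-06, and adjusted p = 0.567 with an estimated correlation). Amino acid synthesis had medians of -0.32 (adjusted p = 8.75e-06) and -0.34 (adjusted p = 0.00164) in these species, and fatty acid synthesis of E. bolteae -0.74 (adjusted p = 2.99e-05), with adjusted p = 0.958, 0.748 and 0.748 with an estimated correlation. Adjusted over the lists alone, 1 purine and 4 amino acid synthesis genes of B. producta were lower and none of E. bolteae.

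Genes for the uptake, activation, hydration and oxidation of long-chain fatty acids were called after uLCFA only in B. thetaiotaomicron, downward, with a median of -0.68 over 9 genes (camera adjusted p = 0.0115, 0 adjusted over the list alone, and adjusted p = 0.844 with an estimated correlation). That call ended without PBS gavage replicate 2 (adjusted p = 0.209) and without uLCFA replicate 1 (adjusted p = 0.2002). In P. distasonis, B. producta and E. bolteae the same list had adjusted p-values of 0.136, 0.567 and 0.566 and medians of -0.13, 0.41 and 0.07, with 0, 2 and 0 genes higher adjusted over the list alone. The fry test for mixed directions, 1 of the alternatives, gave it adjusted p = 0.216 in B. thetaiotaomicron, 0.226 in P. distasonis, 0.00161 in B. producta and 0.000961 in E. bolteae. After flagellin camera did not call it in any species (adjusted p = 0.127, 0.0696, 0.71 and 0.706), while the fry test for mixed directions gave adjusted p = 6.33e-05, 0.00225, 0.0275 and 0.224 and the directional fry test 0.00536, downward, in B. thetaiotaomicron. It had 3 of 8 genes lower in B. thetaiotaomicron, 2 of 9 in P. distasonis, and 1 of 5 higher in B. producta, oleate hydratase.

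The genes called after flagellin were then read in the uLCFA experiment, which has its own control libraries. Genes that had risen after flagellin had median uLCFA log2 values of 1.69 in B. thetaiotaomicron (318 genes, 94.7% above 0), 1.09 in P. distasonis (233 genes, 97.0%), 1.19 in B. producta (443 genes, 95.5%) and 1.64 in E. bolteae (225 genes, 96.4%), where 52.3%, 52.0%, 55.5% and 50.8% of all tested genes lay above 0. Genes that had fallen had medians of -0.59, -0.36, -0.36 and -0.73 in that order, with 83.1%, 72.4%, 76.9% and 86.8% below 0. Camera called all 8 lists at the preset correlation (largest adjusted p = 8.96e-12), and none with an estimated correlation (smallest adjusted p = 0.0907, largest adjusted p = 0.219). Across genes, which are not independent replicates, Pearson's r was 0.687, 0.516, 0.659 and 0.642 and Spearman's rho 0.598, 0.476, 0.591 and 0.652.

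Single genes are given by value, since none passed the main edgeR fit after uLCFA. Of the named genes, 48 of 49 in B. thetaiotaomicron, 38 of 40 in P. distasonis, 39 of 42 in B. producta and 36 of 38 in E. bolteae had the same sign in both experiments, and in 29, 21, 28 and 24 of them the uLCFA and PBS libraries also did not overlap, where chance gives 16.7% for that direction. Among all tested genes 1535 of 3520, 1433 of 3739, 1757 of 4676 and 1566 of 3713 did not overlap in either direction, where chance gives 33.3%. Oleate hydratase of B. producta stood at 4.93 after uLCFA (SE 0.96, edgeR adjusted p = 0.182), GlnN at -6.34, glutamate dehydrogenase of B. thetaiotaomicron at 4.10, and the iron-binding protein of E. bolteae at 4.50, whereas its small acid-soluble spore protein stood at 0.00. The medians depended on uLCFA replicate 2. Without it the risen genes had medians of 1.05, 0.27, 0.13 and 0.64, and the fallen genes of B. producta and E. bolteae -0.22 and -0.46. Without uLCFA replicate 1 the fallen genes had medians of -1.01 in B. thetaiotaomicron, -0.73 in B. producta and -1.39 in E. bolteae.

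**Figure D5:**
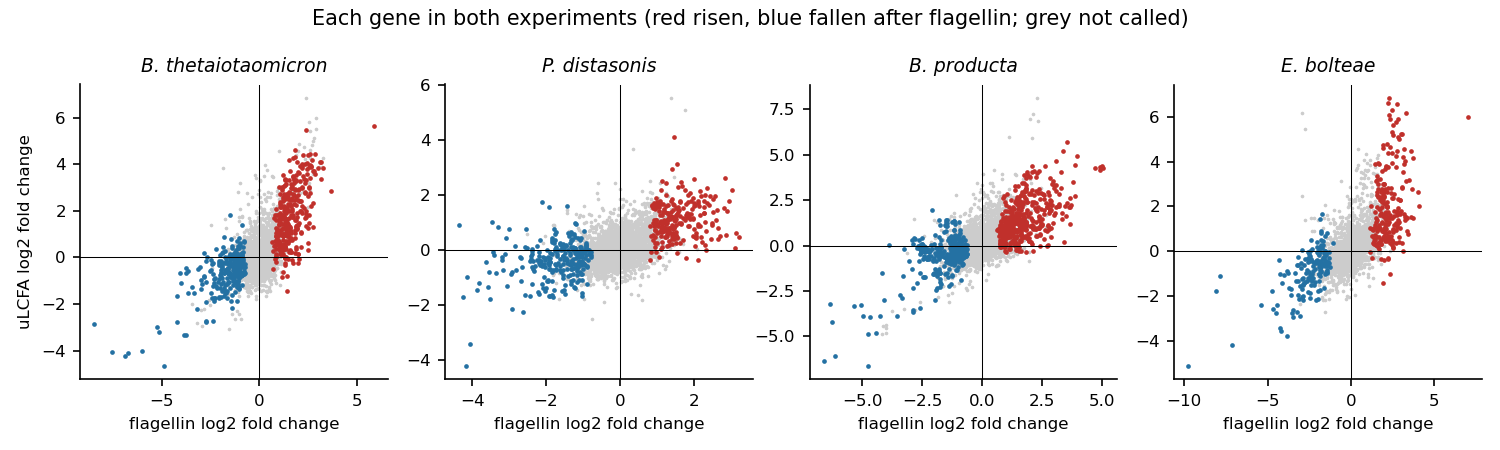
Fitted log2 fold change after flagellin (horizontal) and after uLCFA (vertical) of each gene tested in both experiments, per species. Red and blue points are genes that rose and fell after flagellin and grey points the others. Of the red points 94.7% to 97.0% lie above 0 on the vertical axis.

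The difference between the responses was tested directly. Of 3686, 3724, 4658 and 3533 genes, 0 in B. thetaiotaomicron, 0 in P. distasonis, 1 in B. producta and 0 in E. bolteae passed the edgeR interaction test, with 360, 282, 358 and 269 at an unadjusted p under 0.05, and DESeq2 called 19, 40, 42 and 14. The gene of B. producta is a hypothetical protein, named after its values were seen, with a flagellin value of -2.10 (SE 0.84), a uLCFA value of 6.14 (SE 0.73) and a difference of -8.24 (SE 1.02, adjusted p = 0.00764). Its call was not kept in every fit with 1 library left out. Without uLCFA replicate 2 the test called 227 genes in B. thetaiotaomicron and 22 in P. distasonis, and without uLCFA replicate 1 it called 57 in B. producta. Called in both experiments with the same sign were 0 genes, since the main edgeR fits made no call after uLCFA.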

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

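Groups of 4 libraries were searched for single libraries that stood apart, by the gap to the nearest other library divided by the range. Of 374 groups 21 passed, where 5% are expected by chance, and 14 of the 21 lay in flagellin replicate 2. In B. producta after PBS injection these were cysteine synthase with a ratio of 0.881 (129 CPM in replicate 2, others 19.8 to 32.8), V-type ATP synthase subunit A with 0.963 (778 CPM in replicate 2, others 568 to 576) and MutL with 0.872 (82.7 CPM in replicate 1, others 89.1 to 90.1). In E. bolteae after PBS injection threonyl-tRNA synthetase had 0.842 (444 CPM in replicate 1, others 249 to 280).

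After flagellin, several low genes had counts in 1 library alone, which gives a ratio of 1. These were the small chain of glutamate synthase of B. thetaiotaomicron (20.1 CPM in replicate 4) and, in replicate 2, the tryptophan synthase alpha chain of P. distasonis (6.00 CPM), an amidotransferase subunit of B. producta (0.555 CPM), and the diaminopimelate aminotransferase (36.6 CPM) and enoyl reductase (54.9 CPM) of E. bolteae. Ribosomal protein S4 of B. thetaiotaomicron had 0.878 (1354 CPM in replicate 2, others 794 to 863) and the chaperone CbpA of P. distasonis 0.900 (237 CPM in replicate 2, others 476 to 502). In B. producta the lantibiotic transport ATP-binding protein srtF had 0.859 (231 CPM in replicate 3, others 26.1 to 55.1), ribosomal protein S1 0.898 (114 CPM in replicate 4, others 86.6 to 89.4) and MutL 0.838 (60.5 CPM in replicate 2).

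In E. bolteae flagellin replicate 2 was the highest library for phenylalanyl-tRNA synthetase (ratio 0.847, 73.2 CPM, others 21.1 to 29.1), V-type ATP synthase subunit C (0.914, 110 CPM, others 12.7 to 21.1), ribonucleotide reductase (0.847, 36.6 CPM), MutS (0.839, 201 CPM, others 87.2 to 105) and a hypothetical protein (0.883, 256 CPM, others 52.7 to 76.5). In B. producta it was the lowest library for the shares of the 2 most abundant hypothetical proteins (0.925, 32.9%, others 39.3% to 39.8%, and 0.918, 24.1%, others 31.0% to 31.6%). The interaction test between the experiments gave 1 gene, in B. producta.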

How the results depend on the processing

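Counts of changed genes after flagellin moved by more than 1.5 times in these fits: 371 (main 585) for B. thetaiotaomicron in the joint fit, 2969 (main 771) for B. producta with library totals, and for E. bolteae (main 392) 159 with at least 10 counts in every library, 714 with DESeq2, 186 with a replicate block and 183 after thinning. With 1 library left out the counts ranged over 430 to 736 in B. thetaiotaomicron, 279 to 954 in P. distasonis (main 488), 480 to 1256 in B. producta and 118 to 955 in E. bolteae. For uLCFA (main 0 in each species) DESeq2 called 225, 25, 213 and 185 genes in B. thetaiotaomicron, P. distasonis, B. producta and E. bolteae and the joint fit 241, 9, 127 and 58. The replicate block called 4 in P. distasonis and 222 in B. producta, and no filter 101 in E. bolteae. Leave-one-out counts ranged over 0 to 921, 0 to 895, 10 to 1382 and 9 to 852. Gene lists called after flagellin (main 30) were 3 with estimated correlations, 63 with fry mixed and 18 with the lists as first written. After uLCFA (main 28) they were 0 with estimated correlations, 0 with fry directional, 11 with fry mixed and 16 as first written, where fatty acid synthesis of B. producta and E. bolteae after flagellin lost its call (adjusted p = 0.104 and 0.946). Leave-one-out counts of lists were 27 to 36 after flagellin and 22 to 36 after uLCFA. With estimated correlations the calls of flagellin genes in the uLCFA libraries were lost, at unchanged medians of 1.69 and -0.59, 1.09 and -0.36, 1.19 and -0.36, and 1.64 and -0.73 for risen and fallen genes. Those medians ranged, with 1 library left out, over 1.05 to 2.01 and -1.01 to -0.51 in B. thetaiotaomicron, 0.27 to 1.47 and -0.54 to -0.28 in P. distasonis, 0.13 to 1.63 and -0.73 to -0.22 in B. producta, and 0.64 to 2.30 and -1.39 to -0.46 in E. bolteae. The interaction gave 19, 40, 42 and 14 genes with DESeq2, 3 in E. bolteae with no filter, and leave-one-out counts of 0 to 227, 0 to 22, 0 to 57 and 0 to 1. Share differences after flagellin turned sign without the 10 most abundant genes in B. thetaiotaomicron (0.480 points) and E. bolteae (1.58), and without features above 5% in E. bolteae (1.67). With 1 library left out they ranged over -6.68 to -4.21, -13.4 to -9.37, 15.6 to 22.6 and -4.23 to -0.116 points after flagellin, and -11.1 to -10.3, -16.3 to -7.25, 14.0 to 30.05 and -2.86 to 3.82 after uLCFA, the latter turning sign in E. bolteae. In B. producta an alpha-L-arabinofuranosidase, a thioredoxin and methionine sulfoxide reductase A turned to -0.31, -0.41 and -0.76 with library totals. Without uLCFA replicate 2 the uLCFA direction turned for ribosomal proteins in B. thetaiotaomicron (adjusted p = 0.667, range with 1 library left out 1.20e-11 to 0.667), P. distasonis (3.68e-05, range 1.24e-17 to 0.0561) and E. bolteae (1.17e-05, range 7.10e-14 to 0.00176). It also turned for purine and pyrimidine synthesis in B. thetaiotaomicron (range 0.000212 to 0.594) and for aminoacyl-tRNA synthetases and translation factors in E. bolteae (range 1.97e-05 to 0.790), at the upper end of each range. The cause was not tested for any of these shifts. The replicate numbers are not known to pair samples. In the injection experiment no library correlated best with its own number (correlations -0.341 to 0.211), and in the gavage experiment, where 2 pairs leave little choice, all did (0.0605 to 0.273). Besides the counts above, the replicate block ended the P. distasonis ATP synthase call after flagellin (0.0522). Omitting ribosomal and transfer RNA features gave 584, 483, 772 and 392 genes called after flagellin (main 585, 488, 771 and 392). Only 1, 1, 2 and 2 features are typed as RNA in these species. Ribosomal RNA counted under features named as proteins was not tested.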

Other observations

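Chosen after results were seen were the ammonium assimilation list and its tests, thinning with the tests of depth, the omission of features above 5%, the test of dominant features after uLCFA and the lists as first written, while the functional lists were planned. After uLCFA, flagella and chemotaxis genes of E. bolteae had a median log2 value of 1.04 over 34 genes (camera adjusted p = 0.000176, and adjusted p = 0.748 with an estimated correlation), a call that ended without PBS gavage replicate 2 (0.0782). Efflux and drug resistance genes had medians of 1.08 in B. thetaiotaomicron (53 genes, adjusted p = 0.000287, and adjusted p = 0.844 with an estimated correlation, 0.162 without uLCFA replicate 1) and 0.30 in P. distasonis (66 genes, adjusted p = 0.0474, and adjusted p = 0.936 with an estimated correlation, 0.0575 without PBS gavage replicate 1, and 0.142 with the list as first written). Glycoside hydrolases and sulfatases of B. producta had a median of 0.53 over 90 genes (adjusted p = 0.00421, and adjusted p = 0.958 with an estimated correlation, 0.477 without uLCFA replicate 2).

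An arbitrary grouping of the libraries did not account for the 585, 488, 771 and 392 genes called after flagellin: among the 35 ways to split the 8 libraries into 4 and 4, the real split was the only 1 that reached its count in each species, and the highest other counts were 43 in B. thetaiotaomicron, 0 in P. distasonis, 0 in B. producta and 0 in E. bolteae. For gene lists it was not excluded, since 5 of 35 splits called at least the real 30 lists, with up to 35. Without features above 5%, the lowest median ratio of the called genes' folds to the main fit was 0.981, and 574, 448, 748 and 378 stayed called. TMM already trims such features, so this refit could hardly differ and does not decide whether they account for the genes. With library totals 230 of 771 B. producta genes turned sign. All libraries of a species were also thinned to the same total. Of the genes, 468, 424, 701 and 210 could then be tested, and 397, 376, 622 and 173 stayed called. Median fold ratios among those tested were 0.989, 1.00, 1.00 and 0.986, but random thinning keeps expected folds, so these ratios could not decide on depth. Calls that were kept did not need unequal totals. Depth stays open for the other genes, above all in E. bolteae, where under 80% were tested, a bound set after values were seen. The totals include the dominant features, so the remaining genes were not brought to equal depth. The groups may still differ by cage or day, which the labels do not give.

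The median of the ammonium assimilation genes lay below 0 after flagellin in all 4 species, on a list assembled after the flagellin values were seen and so a hypothesis for other data. Medians were -5.23, -2.17, -0.67 and -0.83 over 9, 10, 14 and 12 genes, with 24 genes fallen and 5 risen, and for E. bolteae camera with an estimated correlation gave p = 0.195. In each species some fallen genes lie close together in the order of the identifiers and need not be independent. Of the 24 fallen genes, 23 stayed called after thinning and 24 without features above 5%. This count was chosen after a test on the medians set earlier gave -0.59 and -0.68 in B. producta, between its bounds. It covers only genes picked because they had been called. The 23 did not need unequal library totals to be called. TMM trims dominant features, so the refit without them could hardly differ and decides nothing about them. After uLCFA the medians were -3.22, -0.303, -0.51 and -0.87 in the same order (camera p = 2.22e-07, 0.0856, 1.64e-05 and 0.00609, and p = 0.0848, 0.214, 0.0444 and 0.106 with an estimated correlation). Whether the list also changed after uLCFA stays open, since P. distasonis missed 0.05 and turned to 0.29 without uLCFA replicate 2, and B. producta and E. bolteae missed it without uLCFA replicate 1 (0.0869 and 0.0965).

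Genes risen after flagellin had medians above 0 after uLCFA in all 4 species, but with an estimated correlation no list passed (adjusted p = 0.0907 in B. thetaiotaomicron and 0.219 in the others). Much of this may rest on uLCFA replicate 2, since without it the risen genes' medians fell to 0.619, 0.253, 0.111 and 0.389 of their size, the lowest in B. producta, although all stayed above 0. A shift of all genes alike, as dominant features can give through scaling, did not account for it in the fit of all gavage libraries. There the risen genes' median exceeded that of all tested genes by at least 1.06, where library totals moved all genes by -0.34 at most. Whether dominant features acted unevenly on the risen genes cannot be told from this difference, in which a common shift cancels. After thinning the medians were 0.987, 1.02, 0.993 and 1.03 of their size over 316, 233, 438 and 213 genes. Random thinning keeps expected folds, so these ratios could not decide whether library depth mattered.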
